A study of Homo sapiens and Mus musculus with 7 samples.

How the data were processed

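Single-cell RNA was sequenced from 3 libraries of whole C57BL/6 mouse kidney at embryonic day 18.5 and 4 libraries of human kidney organoids at day 25 of a stem cell differentiation, all prepared with 10x Chromium v2 kits. Per the labels, kidneys were dissociated with Accutase and organoids with trypsin, so the enzyme was the same split as the groups. The deposited values were counts of unique molecular identifiers (UMIs) per gene and cell, made by the authors with Cell Ranger 1.3.1 on the builds mm10 and hg38 according to their processing notes. The notes give no annotation release, no filter on cells and no statement of whether libraries were equalised in depth when combined. Organoids 1 to 3 shared a table and organoid 4 had a table of its own. Every entry of the 3 deposited tables was the same as in the deposited matrix files (0 entries differed), and those matrices also held the barcodes below the called cells for kidneys and organoids 1 to 3.

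Cells with fewer than 500 detected genes or over 20% mitochondrial counts were left out. The kept cells were 1531 of 1787, 2097 of 2600 and 2011 of 2365 in the kidneys and 2449 of 2450, 2232 of 2233, 2321 of 2321 and 1421 of 1421 in the organoids. Of the kidney cells left out, 240, 470 and 333 had fewer than 500 genes, and haemoglobin made up most of their counts. Genes were matched between species by symbol, 15861 by the same symbol and 15863 in all, which held 92.6% to 94.0% of the UMIs of a library. Depth sets the precision of small shares: intervals are exact Clopper-Pearson at 95%, a count of 0 allows a share of 3 counts of the total, and both cover counting error only.

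Each species was clustered on its own with scanpy 1.11.5: log-normalised counts, 2000 variable genes, 30 principal components, 15 nearest neighbours and Leiden clusters (leidenalg 0.10.2) at resolution 1. A cluster took the class of a marker list when at least 3 of its markers were at least 2-fold higher than elsewhere and detected in at least 10% of its cells. Clusters that met no list stayed unnamed, as did organoid clusters with more leading genes of another class, which held 15.0% ± 4.07 (SD, n = 4) of organoid cells. Before that, clusters with no class were set once more against the named clusters of other classes, for the stroma and perivascular lists alone. Those that met such a list took that class, unless at least 3 of their 10 leading genes were cell cycle or histone genes. The latter formed a cycling class of their own. These thresholds and the rules that left clusters unnamed were set with the data at hand, not in advance. Classes are therefore named "-like" from markers, not from the labels.

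Shares of cells and of cycling cells were compared with two-sided exact permutation tests over the 35 splits of the 7 libraries into groups of 3 and 4 (scipy 1.17.1), with Benjamini-Hochberg adjustment over the classes. The chance that groups of these sizes show no overlap is 5.71%. Genes were compared on counts summed per library, over whole libraries or over the cells of a class in libraries with at least 20 such cells. The test was edgeR 4.0.16's quasi-likelihood test with TMM factors and filterByExpr, at a false discovery rate of 0.05. Ratios of classes were tested as the interaction of class with group, with the library as a block. Levels are CPM, computed here from the summed counts. Those of the gene comparisons were scaled with the TMM factors. Levels in free RNA and the levels by class in the closing section used plain totals, so these scales differ. The median log2 change over all genes was 0.25 in podocyte-like cells and 0.24 in the podocyte to stroma ratio, and single changes there are to be read against that shift. Where a group had no counts of a gene, a fold is given against a floor of 3 counts over the group, and where it had 1 to 3 counts a ratio with its exact counting interval.

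Gene lists were fixed before the data were examined, as were the marker lists, the tests and the alternatives, except those stated in the closing section. They covered markers of kidney cell types and of neural, muscle, cartilage, glial, melanocyte, erythroid, immune and pluripotent cells, and programs such as the cell cycle, cholesterol synthesis, interferon response, posterior HOX genes and proximal tubule transporters. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. Genes were named by a rule: in each list up to 4 members with the largest change among those past the threshold with no overlap between groups, the 6 highest and 6 lowest of the remaining abundant genes, and any member of the slit diaphragm, posterior HOX, GDNF and RET and transporter lists. Cycling cells had at least 2 UMIs of 10 mitotic genes after thinning to 2000 UMIs. Free RNA was profiled from barcodes with 1 to 50 UMIs.

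The edgeR fits were tested on simulated data with known changes in a small share of genes, in both directions and at a fixed spread. In the real whole libraries most genes were called, a setting that these rates do not cover. In whole libraries 71.0% of genes changed by a log2 fold of 1 and 100% of those changed by 2 were recovered, with 6 false of 177 calls. In podocyte-like cells 17.0% and 75.8% were recovered (2 false of 88 calls), and in the tubule to stroma ratio 27.0% and 93.0% (5 of 125). The alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, each library left out in turn, other cluster resolutions and cell filters, classes from markers without clusters, other thinning depths and a replicate block. Nephron progenitor-like cells could not be compared within the class because no organoid cluster held them at resolution 1. The doublet caller of scanpy marked under 0.6% of cells and was treated as not having worked. XIST and Y-linked genes were left out of the tables. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3. Results for a few named genes are not reported here.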

Results

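Gene expression was measured in single cells of the developing mouse kidney in late gestation (E18.5) and of human kidney organoids at day 25 of differentiation, to compare the cell types that the organoids hold with those of the embryonic kidney. Kidney organoids are cultures of pluripotent stem cells that form nephron-like structures. There were 3 libraries of C57BL/6 kidney and 4 libraries of organoids from the stem cell line labelled C32. The kept cells numbered 1531, 2097 and 2011 in kidneys 1 to 3 and 2449, 2232, 2321 and 1421 in organoids 1 to 4. They held between 22807213 and 29132555 UMIs per kidney library and between 23028437 and 29612669 per organoid library. The median depth per cell was 11857, 10977 and 12013 UMIs in the kidneys and 9420, 8897.5, 8938 and 14168 UMIs in the organoids. Organoid 4 came in a table of its own whose shallowest cell had 10077 UMIs, against 3229 to 3397 UMIs in organoids 1 to 3. Genes are given by their human symbols, and 15863 genes were matched between the species. Species was the same split as kidney against organoid. Every compared gene is in both annotations, but a gene at 0 in a species cannot be told from one that its annotation covers poorly. The labels do not say whether libraries of a group were separate animals or cultures, so every p describes the spread between these libraries.

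Nephron progenitor-like cells, the population that renews and feeds the growing kidney, made up 21.8% ± 5.47 (SD, n = 3) of kidney cells. By the marker lists, no organoid cluster took this class at resolution 1 (n = 4). The largest organoid library held 0 of 2449 cells, which by counting error alone allows up to 0.122% in that class. That limit does not cover the choice of clusters. Finer clusters (resolution 2) placed 1.21% to 1.43% of organoids 1 to 3 and 0.211% of organoid 4 in that class. Ureteric and collecting duct-like cells were 4.89% ± 0.72 of kidney cells and erythroid-like cells 1.51% ± 0.31, with 0% of each in every organoid. The erythroid share is of kept cells: the gene minimum left out 240, 470 and 333 kidney cells whose counts were mostly haemoglobin. Tubule-like cells, which include early nephron-like clusters, were 27.9% ± 4.07 of kidney cells and 8.95% ± 11.1 of organoid cells. Organoids 1 to 3 held 3.18% to 3.53%. Organoid 4 held 25.6%, with 344 of those 364 cells in an early nephron-like cluster. Podocytes, the filtering cells of the glomerulus, were 1.00% ± 0.45 of kidney cells and 7.61% ± 4.97 of organoid cells. Organoids 1 to 3 held 9.86% ± 2.56 podocyte-like cells and organoid 4 held 0.844%. Endothelium-like cells were 3.61% ± 0.71 in kidneys and 8.29% ± 0.43 in organoids, with no overlap between the libraries of the groups. Cells of tissues outside the kidney appeared in organoids and in no kidney cluster: cartilage-like 5.81% ± 3.87, skeletal muscle-like 2.69% ± 1.71 and neural-like 0.80% ± 0.49.

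Stroma-like cells were 20.2% ± 1.49 of kidney cells and 22.4% ± 12.8 of organoid cells, with 28.7% ± 1.55 in organoids 1 to 3 and 3.24% in organoid 4. Perivascular and smooth muscle-like cells were 6.03% ± 0.48 against 4.51% ± 3.02, with 5.97% ± 0.98 in organoids 1 to 3, so that the difference was -0.06 without organoid 4. Immune-like cells were 4.20% ± 0.65 in kidneys and 0.952% ± 0.713 in organoids. A class of cycling cells with no named lineage held 5.46% ± 0.25 of kidney cells and 13.7% ± 0.51 of organoid cells. Its clusters met the stroma or perivascular list only against other classes, and were kept out of those classes for their cell cycle genes. Cells of clusters that stayed unnamed were 3.39% ± 0.67 in kidneys and 24.3% ± 15.1 in organoids, and 46.9% of organoid 4. An exact permutation test over the 35 splits of the 7 libraries gave its smallest possible p of 0.0286 for the nephron progenitor, ureteric, erythroid, immune, endothelial and cycling classes, with an adjusted p of 0.0667. The exact adjusted p was 0.08 for cartilage, skeletal muscle, neural and unnamed cells, 0.109 for tubule, 0.133 for podocyte, 0.677 for perivascular and 0.914 for stroma-like cells. No class passed the adjusted threshold of 0.05. The sign of the stroma-like and of the perivascular difference turned under other settings of the clustering, and the stroma-like one was -0.256 without organoid 2 and -0.265 without organoid 3.

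**Figure D1:**
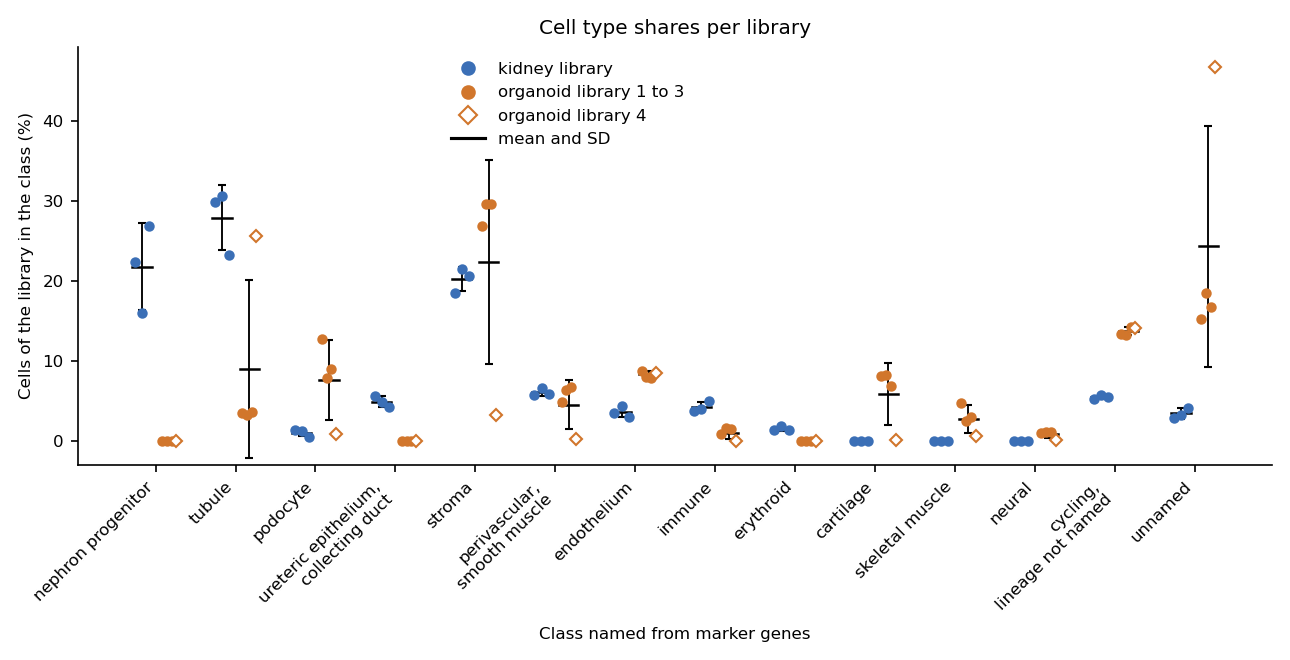
Percent of the kept cells of each library in each class named from marker genes, for kidneys 1 to 3 and organoids 1 to 4, with the mean and SD of each group. Nephron progenitor-like cells were 16.02% to 26.9% of each kidney library and 0% of each organoid library, and organoid 4 stood apart from organoids 1 to 3 in tubule, stroma and unnamed cells.

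The profile of each organoid class was set against all kidney classes to ask which kidney cell type it most resembled. Endothelium-like and tubule-like organoid cells correlated best with the kidney class of the same name in 12 of 12 pairs of libraries, podocyte-like cells in 6 of 6 and immune-like cells in 9 of 9. Spearman's rho across genes was 0.296 to 0.363 for the endothelial, 0.243 to 0.29 for the tubule and 0.248 to 0.26 for the podocyte pairs. Organoid stroma-like cells were closest to kidney stroma in 8 of 12 pairs, and organoid perivascular cells in 2 of 9 to kidney perivascular cells and in 7 to kidney stroma. Organoid cartilage was closest to kidney stroma in 9 of 9 pairs, and organoid neural and muscle cells were closest to nephron progenitors in 9 of 9 pairs each. These are descriptions over genes that are not independent replicates, and no test was made of them.

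Whole libraries were compared to see which genes of each cell type and program the organoids carried, whatever the clusters. Of proximal tubule markers 0 rose and 10 of 10 fell (camera adjusted p = 3.5e-06, and 0.705 with an estimated correlation). Among them the phosphate transporter SLC34A1 fell from 103 ± 23.6 to 0.0863 ± 0.036 CPM (counts scaled to library size with TMM factors, mean ± SD, n = 3 and 4). UMOD, the uromodulin of the loop of Henle, was at least 391-fold lower. The podocyte gene PODXL (podocalyxin) rose by a log2 fold change of 3.98 ± 0.52 (SE, organoid over kidney). CITED1 and SIX2, which mark nephron progenitors, fell from 223 ± 52.7 to 4.68 ± 0.67 and from 63.7 ± 17.4 to 5.46 ± 1.58 CPM.

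Loop of Henle and distal tubule markers had 0 of 9 members higher and 9 lower, and ureteric and collecting duct markers 0 of 10 higher and 8 lower, with CALB1 at -8.79 ± 0.40 and the GDNF receptor RET at -3.94 ± 0.40. Nephron progenitor markers had 1 of 7 higher and 6 lower, and early nephron markers 1 of 8 higher and 3 lower, with WNT4, which drives the conversion of progenitors to epithelium, at -5.46 ± 0.38. Podocyte markers had 7 of 8 higher and 1 lower. Endothelial markers had 7 of 10 higher and 1 lower, among them KDR, a VEGF receptor, at 1.44 ± 0.17, stroma markers 2 of 10 higher, among them PDGFRA at 2.24 ± 0.23, and perivascular markers 2 of 7 higher, with a median of -0.12 and a mean of 0.10. Immune markers had 1 of 9 higher and 8 lower, with CSF1R, the macrophage growth factor receptor, at -6.11 ± 0.46. The erythroid list had too few measured members for a set test, and ALAS2, the heme enzyme of red cells, was at least 1292-fold lower.

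Markers of tissues outside the kidney were counted in the same way. All 7 cartilage markers rose, with CNMD (chondromodulin) at 6.80 ± 1.06 and COL9A2 at 5.88 ± 0.54, and 9 of 10 skeletal muscle markers rose, with the cardiac and embryonic muscle actin ACTC1 at 8.52 ± 1.07. Neural markers had 6 of 8 higher and 1 lower, with the neuronal RNA-binding protein ELAVL3 at 3.85 ± 0.62, and neural crest and glia markers 3 of 4 higher and 1 lower. Pluripotency markers had 4 of 5 higher and 1 lower, with L1TD1, an RNA-binding protein of stem cells, at 4.30 ± 0.41. The melanocyte list had too few measured members for a set test, and PMEL stood at 2.24 ± 0.31. The set test camera called, besides the proximal tubule list, the ureteric (adjusted p = 0.000908), loop of Henle (0.00381) and cartilage (0.0377) lists, and none of them with an estimated correlation (lowest adjusted p = 0.705). Camera gave 0.0863 for nephron progenitor, 0.0928 for podocyte, immune and skeletal muscle, 0.0963 for pluripotency, 0.117 for endothelium, 0.118 for neural, 0.253 for early nephron, 0.616 for perivascular, 0.633 for neural crest and 0.664 for stroma markers.

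Among the programs, 12 of 17 proximal tubule transporters fell and 1 rose, and the organic anion transporter SLC22A6 was 1580-fold lower on 2 organoid counts (95% counting interval 437 to 13050). In cholesterol synthesis 10 of 15 genes rose and 1 fell, with FDFT1 (squalene synthase) at 1.99 ± 0.09 and SQLE at 1.78 ± 0.10. Of 14 immediate early and dissociation stress genes 8 fell and 1 rose, with EGR1 at -2.85 ± 0.31. Camera called these 3 lists (adjusted p = 0.000158, 0.0369 and 0.0382). None of the 3 calls held with an estimated correlation (adjusted p of at least 0.705). Of 11 genes of GDNF and RET signalling, the cue for ureteric branching, 9 fell and 1 rose (0.0863), with GDNF at -3.24 ± 0.35 and GREM1, a BMP antagonist, at 5.83 ± 0.19. Slit diaphragm genes had 11 of 15 higher and 2 lower (0.0928), cell cycle genes 4 of 16 higher and 9 lower (0.11), and posterior HOX genes 2 of 10 higher and 4 lower (0.193), with HOXD11 at -2.09 ± 0.11 and HOXA9 at 0.78 ± 0.14. The retinoic acid list had 4 of 11 higher and 7 lower (0.494), with CRABP1, a retinoic acid binding protein, at 5.71 ± 0.57. The unfolded protein list had 6 of 13 higher and 4 lower (0.494), with TRIB3 at 5.24 ± 0.19 and the chaperone HSPA5 at -1.88 ± 0.24.

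The remaining programs were not called by camera. Glycolysis and hypoxia genes had 2 of 17 higher and 10 lower (adjusted p = 0.235) and fatty acid oxidation genes 3 of 13 higher and 7 lower (0.261). Notch genes had 4 of 12 higher and 6 lower (0.621), WNT targets 4 of 11 higher and 3 lower (0.621), and HOX genes of groups 4 to 8 had 4 of 15 higher and 5 lower (0.664). Interstitial matrix genes had 5 of 18 higher and 2 lower (0.715), and glomerular basement membrane genes 6 of 13 higher and 4 lower (0.776; median 0.09, mean -0.155, test downward). Interferon response genes had 4 of 10 higher and 3 lower (0.908; median 0.40, mean -0.23, test downward). Adjusted over the list alone, these counts were the same in whole libraries except for stroma markers (1 higher, 0 lower), endothelial markers (8 and 1), immediate early genes (0 and 7), HOX groups 4 to 8 (4 and 4), WNT targets (4 and 2), basement membrane (6 and 5) and matrix (4 and 2). Outside the lists the imprinted genes PEG3 (-10.84 ± 0.21) and MEG3 (-10.32 ± 0.32) and the fatty acid binding protein FABP4 (-8.44 ± 0.60) were among the genes that fell most, and the neuropeptide gene NPW (8.99 ± 0.34) and TCEAL7 (8.28 ± 0.30) among those that rose most. In all, edgeR called 10464 of 13600 genes, 5331 higher and 5133 lower.

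Podocyte-like cells were compared to see whether the filtering cell of the organoid carried the same genes as that of the kidney. The core slit diaphragm gene NPHS1 (nephrin) had 410.4 ± 2.12 CPM in kidneys 1 and 2 and 486 ± 23.2 in organoids 1 to 3 (SD, n = 2 and 3; edgeR adjusted p = 0.198). SYNPO (synaptopodin) had 332 ± 219.9 and 343 ± 21.7 CPM (edgeR adjusted p = 0.882). Its log2 change was -0.50 without kidney 1 and 0.99 without kidney 2, where edgeR took the spread of the single kidney library left from the organoids. PODXL rose from 1009 ± 288 to 2472 ± 164 CPM and the junction protein TJP1 by 2.77 ± 0.21 (log2, SE), whereas CD2AP fell by 0.87. A large contrast lay in CDKN1C (p57), the cell cycle inhibitor that marks the mature podocyte, at 16639 ± 4974 CPM in kidney and 100.6 ± 16.3 in organoid podocytes. PLAT, the tissue plasminogen activator, fell from 739 ± 325 to 3.85 ± 1.7 CPM. BST2 (tetherin), which interferon induces, rose from 3.74 ± 5.3 to 1202 ± 37.1 CPM, a ratio of 279 on 2 kidney counts (95% counting interval 77.1 to 2301), and its level in the free RNA of organoid droplets was 252 CPM.

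Of 14 slit diaphragm and foot process genes 6 were higher and 3 lower in podocyte-like cells (camera adjusted p = 0.158), including KIRREL1 at 3.15 ± 0.46. Of 13 basement membrane genes 4 were higher and 5 lower (0.995): the chain COL4A3 of the mature glomerular membrane fell (-2.82 ± 0.39), and LAMB2 (1.98 ± 0.33) and AGRN (1.93 ± 0.27) rose. Immediate early genes had 0 of 13 higher and 9 lower (5.49e-07; adjusted p = 0.375 with an estimated correlation), with EGR1 at -2.57 ± 0.19 and BTG2 at -2.52 ± 0.19. Posterior HOX genes, which set position along the trunk, had 1 of 8 higher and 6 lower (0.0116; 0.481 with that correlation), with HOXD11 at -3.86 ± 0.52, HOXC10 at -3.54 ± 0.32 and HOXA9 at 1.10 ± 0.22. Interferon genes had 5 of 8 higher and 1 lower (0.0106), and glycolysis and hypoxia genes 4 of 15 higher and 8 lower (0.0418). With an estimated correlation the adjusted p was 0.375 for the interferon list and 0.442 for glycolysis. Counts adjusted over the list alone were 2 higher and 9 lower for immediate early genes, 6 and 1 for interferon genes and 4 and 9 for glycolysis, with the others here the same.

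Further podocyte genes changed in lists that camera did not call. In cholesterol synthesis 9 of 15 rose and 0 fell (adjusted p = 0.0731), with IDI1 at 2.90 ± 0.41 and INSIG1 at 1.97 ± 0.35. In the retinoic acid list 2 of 8 rose and 5 fell (0.156), with the synthetic enzyme ALDH1A2 at -4.18 ± 0.42 and the receptor RARB at -5.36 ± 0.71. NOTCH2 (3.60 ± 0.36) rose, and the Notch modulator LFNG (-5.27 ± 0.66) and the GDNF co-receptor GFRA1 (-5.98 ± 0.62) fell. The chaperone HSPA5 fell by 2.22. Cell cycle genes had 2 of 11 higher and 1 lower (0.995; median 0.38, mean 1.13, test downward; 1 and 1 adjusted over the list alone). Among 9437 genes tested, 2777 were higher and 2007 lower in the 3 organoid libraries than in the 2 kidney libraries with at least 20 podocyte-like cells. S100A4 was at least 103-fold and TPPP3 at least 95-fold higher, against a floor of 3 counts over the group. The kidney values rest on 45 cells.

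Stroma-like cells, the interstitial fibroblasts that surround and instruct the nephrons, were compared between 3 kidneys and 4 organoids. All 15 cholesterol synthesis genes rose (camera adjusted p = 0.000135; 0.481 with an estimated correlation), with IDI1 from 19.7 ± 1.26 to 187 ± 61.1 CPM, FDFT1 at 3.08 ± 0.15 and SQLE at 2.47 ± 0.12 (log2, SE). The retinoic acid list had 4 of 8 members higher and 4 lower (camera adjusted p = 0.922; median 0.71, mean 0.53, test downward). CRABP1 rose from 17.3 ± 7.5 to 1127 ± 141 CPM and CRABP2 by 3.44 ± 0.13, whereas DHRS3, a retinaldehyde reductase, fell from 169 ± 14.4 to 10.7 ± 4.32. GDNF fell from 55.3 ± 1.14 to 1.12 ± 1.02 CPM, and GREM1 was at least 107-fold higher.

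Of 18 interstitial matrix genes 14 fell and 2 rose (camera adjusted p = 0.00309; 0.481 with an estimated correlation): COL14A1 fell from 179 ± 9.69 to 12.9 ± 3.1 CPM and SPARC (osteonectin) from 1381 ± 204 to 232 ± 36.7, and the proteoglycan VCAN rose by 2.43 ± 0.14. Cell cycle genes had 1 of 16 higher and 13 lower (0.00309; 0.481 with that correlation), with CDK1 at -3.06 ± 0.15. Stroma-like cells leave out the clusters led by cell cycle genes, which held 18.7% of stroma-marked cells in organoids and 12.7% in kidneys (exact permutation p = 0.0571, n = 4 and 3), so this list is not free of that placing. Glycolysis and hypoxia genes had 2 of 16 higher and 13 lower (0.00266), with ADM, a peptide hormone induced by low oxygen, at -5.05 ± 0.26 and NDRG1 at -2.75 ± 0.20. The immediate early list had 0.0276 (1 of 14 higher and 9 lower, EGR1 at -3.09 ± 0.13) and GDNF and RET signalling 0.0445 (1 of 10 higher and 8 lower, with SPRY2 at -2.38 ± 0.15 and ETV4 at -2.03 ± 0.21). With an estimated correlation the adjusted p was 0.494 for GDNF and RET signalling and 0.481 for the glycolysis and immediate early lists. The immediate early list had 1 higher and 8 lower adjusted over the list alone, and the other lists of this paragraph had the same counts.

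Of 8 WNT targets in stroma 6 rose and 2 fell (camera adjusted p = 0.102), with LGR5, a WNT receptor component, at 5.87 ± 0.38 and the inhibitor DKK1 at 1.92 ± 0.13. Posterior HOX genes went both ways, 5 of 10 higher and 5 lower (0.922): HOXA9 rose by 1.39 ± 0.11, and HOXD10 (-1.43 ± 0.11) and HOXD11 (-1.30 ± 0.11) fell. Basement membrane genes had 2 of 13 higher and 8 lower (0.0989), with COL4A1 at -1.96 ± 0.12 and NID1 (nidogen) at -2.96 ± 0.11. Interferon genes had 2 of 8 higher and 3 lower (0.922; median 0.04, mean -0.04, test downward). Slit diaphragm genes had 9 of 13 higher and 2 lower (0.228), and PODXL stood at 0.396 ± 0.358 CPM in kidney stroma and 5.61 ± 2.42 in organoid stroma, with 11.8 and 263 CPM in the free RNA of kidneys and of organoids 1 to 3. The imprinted gene PEG3 was 2809-fold lower on 2 organoid counts (95% counting interval 777 to 23200). Of 10836 genes tested 4331 were higher and 4096 lower.

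Tubule-like cells pooled different segments in the 2 systems and were compared between 3 kidneys and 4 organoids. Of 1569 such kidney cells 703 lay in proximal, 547 in loop and distal and 319 in early nephron clusters, and of 602 organoid cells 426 lay in an early nephron cluster and 176 in a proximal one. Organoid 4 held 344 of those 426 and 20 of those 176. The fold changes below therefore include the mix of segments. The transporter SLC34A1 fell from 289 ± 41 to 1.75 ± 1.17 CPM and the glucose transporter SLC2A2 was at least 166-fold lower. The amino acid transporter SLC7A7 rose by 1.35 ± 0.36 (log2, SE). The Notch target HES5 fell from 20.4 ± 2.62 to 0.144 ± 0.288 CPM and NRARP from 50.6 ± 5.93 to 0.657 ± 0.832, and the Notch ligand DLL1 by 3.26. The interferon-inducible gene IFITM3 had 59.6 ± 13.1 CPM in kidney and 1329 ± 190.4 in organoid tubule, against free RNA levels of 501 and 590 CPM.

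Of 18 proximal tubule transporters 12 fell and 2 rose (camera adjusted p = 0.00265; 0.608 with an estimated correlation). Interferon genes had 8 of 9 higher and 1 lower (0.00646; adjusted p = 0.575 with an estimated correlation), and cell cycle genes 0 of 16 higher and 11 lower (0.0106; 0.608 with that correlation), with RRM2 at -2.63 ± 0.20. Slit diaphragm genes had 10 of 15 higher and 3 lower (0.0192; adjusted p = 0.575 with an estimated correlation): PODXL stood at 3.71 ± 0.59 CPM in kidney and 78.8 ± 21.9 in organoid tubule cells, with 263 CPM in the free RNA of organoids. Cholesterol synthesis genes had 6 of 15 higher and 3 lower (0.469) and retinoic acid genes 4 of 9 higher and 5 lower (0.842). Posterior HOX genes had 1 of 10 higher and 4 lower (0.175), with HOXD11 at -3.12 ± 0.22 and HOXD10 at -3.10 ± 0.32. Immediate early genes had 1 of 14 higher and 11 lower (0.0778). Notch genes had 3 of 12 higher and 6 lower (0.175), and matrix genes 9 of 18 higher and 0 lower (0.175). ALDH1A3 fell by 4.67, and CRABP2 (4.68 ± 0.23) and LYPD1 (8.77 ± 1.00) rose. S100G, the calcium-binding protein calbindin-D9k, was at least 4933-fold lower. Of 12142 genes tested 4010 were higher and 3995 lower. Adjusted over the list alone, cholesterol genes had 7 higher and 3 lower, and the other counts were the same.

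Endothelium-like cells were compared between 3 kidneys and 4 organoids. FABP4, a fatty acid binding protein of capillaries, had 6583 ± 725 CPM in kidney and 0.422 ± 0.843 in organoid endothelium, a ratio of 16990 on 3 organoid counts (95% counting interval 5813 to 82400). GPIHBP1, which anchors lipoprotein lipase in capillaries, was 1734-fold lower on 2 organoid counts (95% counting interval 479 to 14340). IFIT1 fell from 87.8 ± 17.8 to 1.11 ± 0.50 CPM and BST2 from 1037 ± 87.1 to 42.4 ± 30.4, so that BST2 differed in opposite directions in endothelium and in podocyte-like cells. All 16 cell cycle genes fell (camera adjusted p = 1.63e-08; 0.367 with an estimated correlation), with CCNB2 from 149.8 ± 28.8 to 6.36 ± 1.46 and CDK1 from 207 ± 56.6 to 16.6 ± 6.54 CPM.

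The cell cycle list aside, camera called the interferon list with 0 of 8 higher and 7 lower (adjusted p = 3.81e-05) and the retinoic acid list with 2 of 7 higher and 5 lower (0.00924). With an estimated correlation the adjusted p was 0.260 for the interferon and retinoic acid lists. The retinoic acid degrading enzyme CYP26B1 was at least 112-fold lower, and DHRS3 fell by 6.76. Posterior HOX genes had 3 of 6 higher and 0 lower (0.196), with HOXC9 at 2.93 ± 0.22 and HOXB9 at 2.19 ± 0.18. Basement membrane genes had 7 of 11 higher and 1 lower (0.423), with COL4A2 at 1.44 ± 0.14, and glycolysis and hypoxia genes had 3 of 15 higher and 10 lower (0.196), with the oxygen sensor EGLN3 at -5.86 ± 0.26 and PGK1 at 3.03 ± 0.18. Unfolded protein genes had 7 of 13 higher and 2 lower (0.552), with TRIB3 at 5.00 ± 0.29. Cholesterol synthesis genes had 6 of 15 higher and 5 lower (0.942), and immediate early genes 2 of 13 higher and 3 lower (0.889; median 0.17, mean -0.21, test downward). HEY1, a Notch target of arterial endothelium, rose from 20.1 ± 8.99 to 297 ± 11.1 CPM, NRARP fell by 3.53, and the matrix protein SPARC fell from 2304 ± 60.3 to 766 ± 80.8. Adjusted over the list alone, basement membrane genes had 8 higher and 2 lower and unfolded protein genes 7 and 3, with the same counts in the other lists of this paragraph. Of 9360 genes tested 3266 were higher and 2876 lower.

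**Figure D2:**
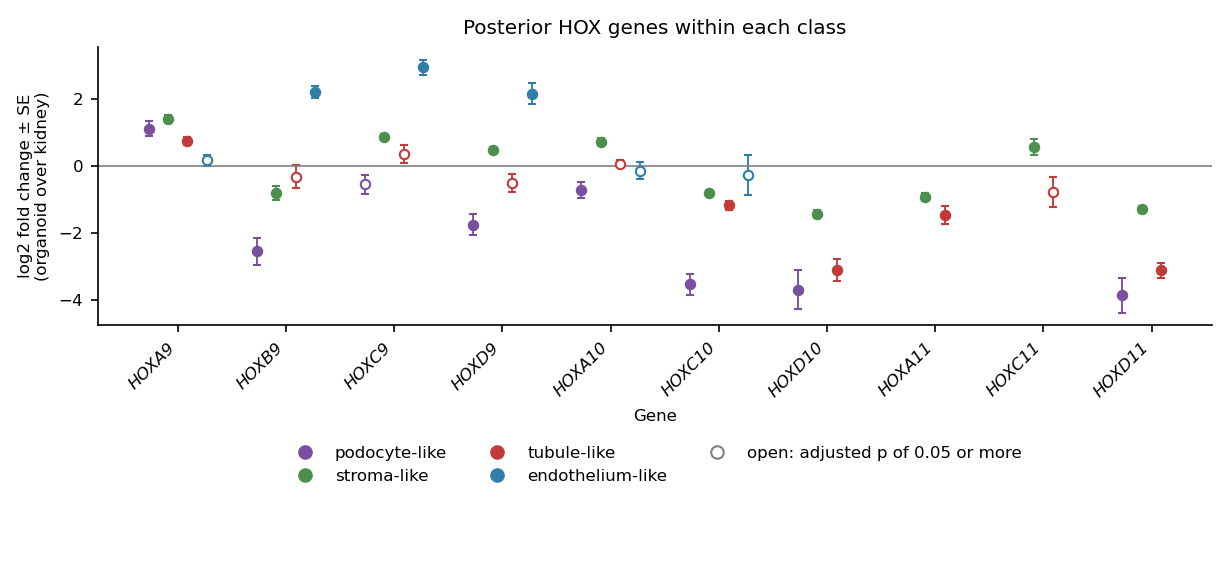
Log2 fold change (organoid over kidney, ± SE from edgeR) of posterior HOX genes within podocyte, stroma, tubule and endothelium-like cells, with filled points past an adjusted p of 0.05. HOXD10 and HOXD11 lay below 0 in podocyte, stroma and tubule-like cells, and HOXB9, HOXC9 and HOXD9 lay above 0 in endothelium-like cells.

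**Figure D3:**
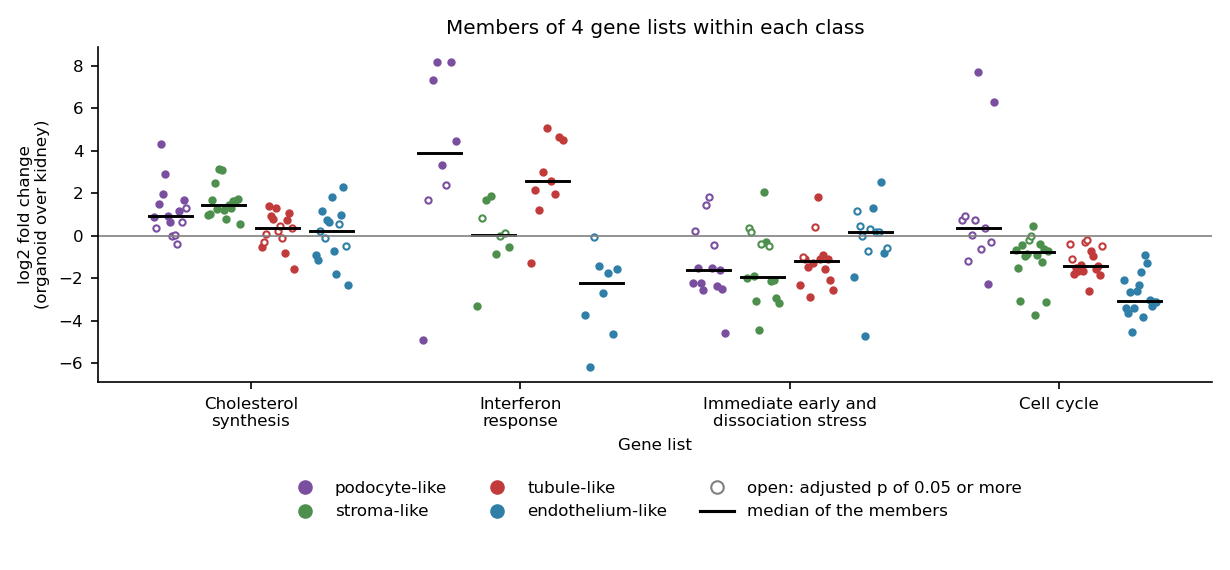
Log2 fold changes (organoid over kidney) of the measured members of the cholesterol synthesis, interferon response, immediate early and cell cycle lists within each class, a point per gene with a line at the median. All 15 cholesterol synthesis genes lay above 0 in stroma-like cells and all 16 cell cycle genes below 0 in endothelium-like cells.

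The ratio of podocyte to stroma-like cells within each library was compared next, since a difference between the species in how well a gene is annotated or captured divides out of it. Of 8 interferon genes 3 ratios rose and 1 fell (camera adjusted p = 0.0487; 0.411 with an estimated correlation), and the log2 ratio of IFITM3 rose by 4.88 ± 0.27 (SE) on 13 kidney podocyte counts. Posterior HOX genes had 0 of 10 ratios higher and 7 lower (0.000135; adjusted p = 0.411 with an estimated correlation), with HOXC10 at -2.74 ± 0.31, HOXD11 at -2.58 ± 0.47 and HOXD9 at -2.21 ± 0.35. Of 13 basement membrane genes 7 rose and 0 fell (0.00166; adjusted p = 0.411 with an estimated correlation), with LAMB2 at 2.14 ± 0.37 and LAMC1 at 1.93 ± 0.22. The slit diaphragm list went both ways, with MAGI2 at -4.57 ± 0.28, TJP1 at 2.80 ± 0.22, ACTN4 at 1.25 ± 0.16 and CD2AP at 1.05 ± 0.20. The Notch target HEY1 (-4.83 ± 0.36) and the WNT effector LEF1 (-5.63 ± 0.58) shifted towards stroma, as did PCP4 (-9.61 ± 0.22) and FXYD6 (-5.53 ± 0.15), and NOTCH2 (3.03 ± 0.45) and NPNT (2.92 ± 0.45), the integrin ligand nephronectin, towards podocytes.

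Of 18 matrix genes 15 rose and 2 fell in this ratio (camera adjusted p = 0.00765; 0.602 with an estimated correlation). Draws made wholly of free RNA were stroma-marked in 26.75% to 31.2% of cases in organoids 1 to 3 and in at most 0.15% in kidneys. The share of free RNA in podocyte droplets was not measured. Any stromal RNA in organoid podocyte droplets would not divide out of these ratios. The slit diaphragm list had 5 of 14 higher and 7 lower (0.533). Adjusted over the list alone, basement membrane genes had 9 higher and 1 lower, matrix genes 15 and 3, interferon genes 4 and 1, and the HOX and slit diaphragm counts were the same. Of 11483 genes tested 1784 ratios rose and 1354 fell. Without kidney 1 the total of 3138 became 1991, with the spread of the single kidney podocyte library taken from the others, and with DESeq2 1138 rose and 1237 fell.

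The ratio of tubule to stroma-like cells was compared in the same way over 3 kidneys and 4 organoids. Of 8 interferon genes 6 ratios rose and 0 fell (camera adjusted p = 8.85e-05; 0.171 with an estimated correlation), with log2 changes of 5.07 ± 0.16 (SE) for IFITM3, 4.22 ± 0.27 for BST2 and 2.03 ± 0.45 for IRF7. Of 15 cholesterol synthesis genes 0 rose and 12 fell (4.92e-08; adjusted p = 0.171 with an estimated correlation), with IDI1 at -2.36 ± 0.35, MVD at -2.26 ± 0.22 and FDFT1 at -1.82 ± 0.18. Of 10 posterior HOX genes 0 rose and 7 fell (0.00484; adjusted p = 0.269 with an estimated correlation), with HOXD11 at -1.73 ± 0.27, HOXD10 at -1.39 ± 0.33 and HOXA9 at -0.65 ± 0.14. Of 18 matrix genes 12 rose and 1 fell (2.8e-06) and of 13 basement membrane genes 7 rose and 1 fell (0.014; adjusted p = 0.269 for both with an estimated correlation), with SPARC at 2.87 ± 0.16, BGN (biglycan) at 3.23 ± 0.20 and NID1 at 2.91 ± 0.36. Free stromal RNA could bear on these ratios as on those of podocytes, and its share in tubule droplets was not measured. A ratio can move through either class. GDNF shifted towards tubule (4.66 ± 0.60) mainly through stroma, with 641 kidney and 22 organoid counts there and 151 and 98 in tubule. The WNT genes LGR5 (-7.14 ± 0.83) and LEF1 (-2.17 ± 0.26) and the Notch ligand DLL1 (-3.79 ± 0.72) shifted towards stroma. Outside the lists, IFITM1 (8.19 ± 0.24), DLK1 (6.77 ± 0.28) and the creatine kinase CKB (6.23 ± 0.23) were among the ratios that rose most, and the BMP and WNT antagonist SOSTDC1 (-6.76 ± 0.21) and SFRP2 (-6.13 ± 0.53) among those that fell most. IFITM1 and IFITM3 are close paralogs, so reads shared between them are possible.

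Of 17 glycolysis and hypoxia genes 8 ratios rose and 1 fell (camera adjusted p = 0.0231), and of 11 WNT targets 2 rose and 5 fell (0.0483). With an estimated correlation the adjusted p of both was 0.269. Adjusted over the list alone, cholesterol genes had 0 higher and 14 lower, matrix genes 13 and 1 and WNT targets 2 and 6, with the other counts the same. Of 12239 genes tested 2135 ratios rose and 2374 fell. With RLE factors 2399 rose and 2125 fell, and with DESeq2 1952 rose and 1647 fell.

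Cycling cells were counted to compare proliferation at equal depth, as cells with at least 2 UMIs of 10 mitotic genes such as MKI67 and TOP2A after each cell was thinned to 2000 UMIs. Among endothelium-like cells 37.9% ± 9.98 (SD, n = 3) cycled in kidneys and 3.56% ± 1.91 (n = 4) in organoids, with no overlap. Among stroma-like cells the shares were 9.80% ± 1.11 and 5.19% ± 0.58, again with no overlap, and among tubule-like cells 30.5% ± 3.08 and 12.04% ± 10.2. Of all cells 26.2% ± 1.90 cycled in kidneys and 19.2% ± 5.72 in organoids, and 27.8% ± 1.75 of kidney nephron progenitor-like cells did. Podocytes, which leave the cycle as they mature, showed 0 cycling cells of 45 in kidneys 1 and 2 and 0.884% ± 0.624 in organoids 1 to 3. Exact permutation tests gave p = 0.0286 for stroma and endothelium (adjusted p = 0.0714), 0.0571 for tubule (0.0952), 0.114 for all cells (0.143) and 0.2 for podocytes (0.2), so that no class passed the adjusted threshold. The podocyte difference turned negative at other depths. Free RNA of cycling cells may add to such shares. The stroma-like share leaves out the cells in the cycling class. Among stroma-marked cells of any cluster 20.7% cycled in kidneys and 21.5% in organoids (exact permutation p = 0.971).

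**Figure D4:**
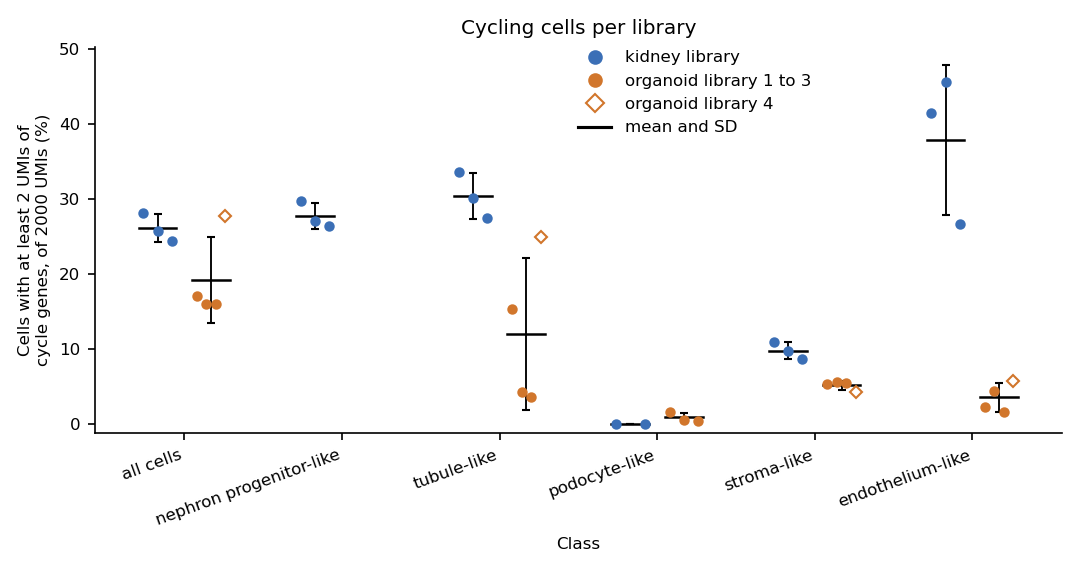
Percent of cells per library with at least 2 UMIs of mitotic genes after thinning to 2000 UMIs, within all cells and within each class, with the mean and SD of each group. Kidney endothelium-like cells lay between 26.7% and 45.7% and organoid endothelium-like cells between 1.65% and 5.79%.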

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

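The tests of explanations and the other splits of this part were chosen after the results were seen, and the counts of genes and the interaction tests before.

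Organoid 4 lay far from organoids 1 to 3 in 6 of 15 measures whose gap to the nearest library passed Dixon's critical value. For a single measure chance gives about 1 in 20. Class shares are parts of the same total, so the measures are not independent and a single shift can move several. The tubule-like cells of organoid 4, most of them in the early nephron-like cluster, were 25.6% of cells, against 3.18% to 3.53% in the others. Its stroma-like cells were 3.24% against 26.95% to 29.6%. Cartilage-like and neural-like cells were 0.0704% each, against 6.89% to 8.199% and 0.98% to 1.08%. Unnamed cells were 46.9% against 15.3% to 18.46%, and 27.8% of all cells cycled, against 16.03% to 17.1%. Its podocyte-like share of 0.844% did not pass the same measure.

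A higher UMI minimum in the table of organoid 4 was set against this pattern, and with that minimum applied to organoids 1 to 3 their lowest podocyte-like share was 6.38%, which argues against depth as the cause for podocytes. The stroma-like share of those libraries narrowed to between 12.97% and 15.2%, so that depth may account for part of that gap. Clusters shared between libraries were tested by classes from markers alone, which gave 3.17% podocyte-like cells in organoid 4 and 8.51% as the lowest of the others. For stroma-like cells the gap was 25.5% of cells, 23.5% from markers alone and 11.8% with genes centred within each library, so the placing of its stroma cells cannot be told apart from a difference in cells. Organoid 4 was the only library of its table, so batch, processing and a difference between cultures stay open and untested.

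Podocyte-like cells were a larger share of organoids 1 to 3 than of kidneys. Kidney podocytes below the UMI minimum of the deposited cells were counted among all barcodes of at least 1000 UMIs: podocyte-marked barcodes were at most 1.17% of them in kidneys and at least 8.78% in organoids. Counting no organoid barcode below the deposited cells as a podocyte still left 6.87% to 10.6%. Deposited cells of organoids 1 to 3 were podocyte-marked in 12.6%, 8.24% and 9.18% of cases. Draws from free RNA were so marked more often, in 19.9%, 12.65% and 14.65% of cases. The organoid count is not above that background, so it cannot settle whether lost kidney podocytes explain the gap. Free podocyte RNA could place podocyte markers in other organoid droplets, and draws from it were podocyte-marked in 12.7% to 19.9% of cases in organoids and 0% in kidneys. The median ratio of the markers in organoid podocyte-like cells to free RNA was at least 8.01 in each library. Those markers also named the cells, so a raised ratio was partly built in and is not an independent check. A difference in yield between Accutase and trypsin is the same split as the groups and stays open, as does a difference between the tissues.

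Fewer cells of the stroma-like and endothelium-like classes cycled in organoids. For stroma, a placing of cycling cells in the cycling class was tested among stroma-marked cells of any cluster, whose share differed by 0.84% of cells (exact permutation p = 0.971, n = 3 and 4). The difference was -2.59 without organoid 4, -0.31 without kidney 2 and between 1.23 and 2.52 with any other library left out. Its sign depends on the libraries. With all libraries the difference of -4.60 in the stroma-like class was not seen in this count, as placing would give. A smaller difference in cycling cannot be excluded. For endothelium the same count gave -34.7% (exact p = 0.0286, the smallest the splits can give), so placing is unlikely to be its cause. Free RNA of cycling cells was bounded by the podocyte-like cells of kidneys 1 and 2, of which 0 of 45 cycled, which allows up to 6.67%. The lower bound of the lowest kidney endothelial share was 16.1%, above that limit. That of the lowest stromal share was 6.16%, so free RNA cannot be told apart from cycling in stroma. Both of these shares were from kidney 3, which the limit does not cover.

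The ratio of podocyte to stroma-like cells differed between organoid and kidney for 3138 genes, and that of tubule to stroma for 4509 genes, by tests of the interaction itself. The real grouping of the libraries called more genes than each of the other splits: only 1 of 35 splits, the real one, gave as many. It called 10464 genes in whole libraries (highest other 2806), 8427 in stroma (5860) and 8005 in tubule (145). In endothelium it called 6142 (2) and in the tubule to stroma ratio 4509 (2347). A share of 1 in 35 is the smallest that these splits can give, so they cannot exclude chance. The real split is also mouse against human, so its lead cannot be read as organoid against kidney alone. The highest other split was always organoids 1 to 3 against the kidneys with organoid 4, so organoid 4 is a structure among the samples.

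Barcodes below the deposited cells, which entered the podocyte count over all barcodes above and no other comparison, held endothelial markers in 16.8%, 23.1% and 21.4% of cases in organoids 1 to 3. Draws from free RNA gave 2.35%, 3.20% and 2.45%, and deposited cells of the same libraries 7.72%, 6.54% and 6.76%. In kidneys 1.499%, 6.32% and 3.76% of such barcodes held them. No biological explanation was tested for these shallow barcodes.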

How the results depend on the processing

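The 2 alternatives without the highest doublet scores and with the UMI minimum of organoid 4 were chosen after seeing the data, and the others before.

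Of 79 alternatives to the 7 counts of genes, 78 stayed within 1.5 times. The podocyte to stroma ratio gave 1991 to 2977 genes with a library left out, and 1991 without kidney 1, where a single kidney podocyte library remained, taken to vary as the organoids do. Of 223 alternatives for class shares 215 kept direction and call. The perivascular difference of -1.52% of cells became 2.73 with genes centred within each library, 1.38 without called doublets, 2.87 with the UMI minimum of organoid 4 and 1.23 from markers without clusters. The stroma difference of 2.16 became -7.8 at resolution 0.5, -2.96 without called doublets, and between -0.265 and 8.54 with a library left out, below 0 without organoid 2 or 3. The cause was not tested. Nephron progenitor-like cells were 0% of organoids, but 1.21% to 1.43% of organoids 1 to 3 and 0.211% of organoid 4 at resolution 2.

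Of 48 alternatives for cycling shares 46 kept direction and call, and with a library left out the call could again not change. The podocyte difference became -2.01 thinned to 1000 UMIs and -6.33 without thinning. The perivascular profile match fell from 2 of 9 pairs to 0 with Pearson's correlation and with variable genes only. Of 266 alternatives for 133 lists 175 were the same, 52 passed only with fry and 36 calls were lost, among them every camera call when the correlation was estimated. With fry, direction turned for the cell cycle in podocytes (fry's adjusted value 0.978), fatty acid oxidation in stroma (0.268) and HOX groups 4 to 8 in stroma (0.577). Of 1809 alternatives for named genes 1807 were the same, and SYNPO in podocytes became -0.50 without kidney 1 and 0.99 without kidney 2.

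With a replicate block, 11377 genes were called in whole libraries, against 11491 without the block in the same libraries. Same-numbered libraries did not deviate together (correlations across genes 0.03, -0.02 and -0.09), so the numbers do not pair them. Comparisons of nephron progenitor-like cells were planned and not run, since no organoid cluster held them at resolution 1. Depth limits small shares, as in podocytes with 45 kidney cells.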

Other observations

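The test of imprinted genes was chosen after PEG3, MEG3 and CDKN1C had been seen, and the genes of the next paragraph were chosen after their values were seen.

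Levels by class located some of the genes that differed in whole libraries. SIX2 was 212 ± 17.9 CPM (SD, n = 3) in kidney nephron progenitors and 40.9 ± 7.27 (n = 3) in organoid skeletal muscle-like cells. CITED1 was 785 ± 30.8 in kidney progenitors and 35.7 ± 1.78 (n = 3) in organoid skeletal muscle-like cells. It was between 5.88 and 87.3 over the libraries in the organoid early nephron-like cluster, which held LYPD1 at 624 ± 143 and DAPL1 at 297 ± 115. CITED1 is on the progenitor list, and this cluster was counted as tubule-like. The lack of a progenitor-like organoid class therefore does not mean that progenitor genes were absent. WNT4 was 164 ± 17.4 CPM in kidney perivascular cells and 84.7 ± 18.4 in tubule, and at most 5.32 in every organoid class. RET was 138 ± 8.66 in kidney ureteric cells and at most 3.34 in organoid classes. SOX2 was 278 ± 51.4 CPM in an unnamed organoid cluster that also held MSX1 at 316 ± 64.5, and 238 ± 74 in neural-like cells. CRABP1 was 5761 ± 2667 in organoid neural-like cells. FOXD1 was 103 ± 22.3 CPM in organoid podocyte-like cells and 39.8 ± 1.36 (n = 2) in those of kidneys.

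A loss of imprinting in the stem cell line was asked about for the low PEG3, MEG3 and CDKN1C in organoids. Of 18 listed imprinted genes 14 were measured in stroma-like cells, with 6 higher and 7 lower and a median log2 change of -0.16. Among 10000 random lists of like expression, 28.6% had a lower median. Such a loss can raise or silence a gene and members went both ways, so the median decides nothing and the explanation stays open. In whole libraries 9 of 16 were higher and 4 lower, and 98.8% of random lists had a lower median.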
